A study of Mus musculus with 8 samples.

How the data were processed

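Total RNA from the bilateral substantia nigra of 8 mice, 2 per group, was hybridised to single-colour Affymetrix whole-transcript arrays, per the labels' protocols. The mice were 6 weeks old, and 300 ng of RNA was labelled. Acupuncture began after the first MPTP injection and was repeated every 48 hr for 14 sessions, with needles at 1 mm for LR3, 3 mm for GB34 and 3 mm at the hips. The labels give 9 animals for the control and MPTP groups, and the arrays come from 2 brains of each group. With 1 array per mouse, p-values measure the spread between mice together with that of dissection, RNA and array. These cannot be told apart. Replicate numbers are those of the labels.

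The deposited values are log2 levels per probe set, in 1 table of 35557 probe sets by 8 arrays, with no column left unused. The submitters' processing notes name Affymetrix Expression Console and RMA. Versions and settings are not given in the sources used here. The deposited log2 columns had medians from 4.09 to 6.00 and different shapes, so no quantile step had brought them to a common distribution. Before the data were examined, the values as deposited had been planned as the main setting. After the medians were seen and before any test was run, quantile normalization between arrays became the main setting, and the values as deposited became an alternative. Signal over background could not be judged, since no detection values were used.

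Gene symbols came from the platform annotation that pairs probe set IDs with genes. Of the probe sets, 21789 had 1 symbol and 1621 had several, and 21698 of those with 1 symbol were found by gene ID in a RefSeq gene table. A further 5529 probe sets from the lowest annotated ID upwards had none listed, and 6618 lay below it. The symbols were checked against the levels in 4 ways: the correlation of probe sets that share a symbol, the levels of gene classes, the chromosomes of neighbouring IDs, and probe sets with equal values. In 225 sets of probe sets with equal values on all 8 arrays, none of the 1555 named pairs shared a symbol. The correlation of levels over the 747 same-symbol pairs found in the RefSeq table was -0.0143. Since the names did not go with the levels, the planned rule of 1 probe set per gene (the brightest), the planned naming of genes and the planned tests of 40 gene lists could not be used. The naming rule had taken, per comparison, up to 8 genes each way with the largest difference among those that passed, filled up with those at unadjusted p under 0.01 without overlap between the groups, the leading members of each list that passed, and 6 markers of dopaminergic neurons, astrocytes and microglia. In its place, the probe set with the largest difference each way at unadjusted p under 0.01 without overlap is given, with its ID as a label only. The planned gene and list tests were run with the names as listed only as alternatives.

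Probe sets from the lowest annotated ID upwards were kept. Of these 28939, 476 equal to an earlier one on all arrays were dropped, and the lowest 25% by mean level were left out, which left 21347. Levels were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group over all 8 arrays, 4 residual degrees of freedom, 4.94 prior degrees of freedom), with Benjamini-Hochberg adjustment over all probe sets within each of 6 comparisons and a threshold of 0.05. Whether arrays of a group were more alike was tested over all divisions of the arrays into groups of the same sizes, on the mean squared log2 difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

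The fit was tested on simulated data for MPTP minus control, over 21347 probe sets with 200 of them changed. Noise was independent and normal, with the moderated spread of each probe set. The fit recovered 23.5% of changes of 1.5-fold, 97.5% of 2-fold and 100% of 4-fold, with 3, 18 and 11 false calls. With control replicate 1 given the average spread of the control pair, shuffled over probe sets, it recovered 1%, 93.5% and 100%. Control replicate 2 kept the moderated spread there, so the full difference of the control pair and its dependence on level were not simulated. Deviations shared by many probe sets of an array were not simulated, so these shares do not carry over to the real arrays. In the real fit 10 probe sets differed by at least 2-fold in this comparison, and 0 passed.

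Alternatives planned before the data were examined were no filter and a filter of the lowest 50%, an intensity trend with robust moderation, array weights, median-centring, the mean of the probe sets of a gene, only the 4 arrays compared, the replicate number as a block, a residual principal component as a covariate, each array left out in turn, an unadjusted threshold and a threshold of fold. Quantile normalization had been planned as an alternative too. The values as deposited and 1 probe set per symbol, both planned for the main fit, were run as alternatives in its place. Added after the data were seen were cyclic loess, all probe sets of the table, crossed replicate numbers, the MPTP arrays divided between comparisons, the values as deposited with only the offset of the array medians removed, and the test of whether arrays of a group were more alike. The 6618 probe sets below the annotated range were tested apart with the same filter, and none of the 4963 kept passed in any comparison (limma, lowest adjusted p 0.422). Their shares at an unadjusted p under 0.05 ran from 2.90% for acupoint minus MPTP to 7.39% for non-acupoint minus control. For MPTP minus control the share was 6.85%. The main fit gave 1.96%, 7.36% and 6.74% in these comparisons, so the higher shares against control were not particular to the annotated range.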

Results

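Gene expression was measured in the substantia nigra, the midbrain region that holds the dopaminergic neurons lost in Parkinson's disease, of male C57BL/6 mice. Each of 8 mice gave 1 single-colour Affymetrix whole-transcript array, and the mice fell into 4 groups of 2. Control mice received saline. The MPTP group received daily injections of MPTP, a toxin used to model parkinsonism in mice, at 20 mg/kg for 4 weeks. The acupoint group received MPTP and manual acupuncture at GB34 and LR3, points of the hind leg and foot, in 14 sessions. The non-acupoint group received MPTP and the same needling at the hips. The number of arrays limits the precision, since each group's spread rests on 2 mice.

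The levels in the table could not be tied to genes. A total of 751 gene symbols were each carried by exactly 2 probe sets, not counting those equal to an earlier one on all arrays. Symbols with more probe sets were left out of this check. The mean log2 levels were uncorrelated across these pairs (r = -0.0105, Spearman's rho = -0.0154, permutation p = 0.772, two-sided, 100000 resamples; pairs of probe sets are not independent replicates). The 1035 probe sets named for olfactory receptors, which are odorant receptors of the nasal epithelium, had a median log2 level of 5.66, and the 217 named for ribosomal proteins, which nearly every cell uses, had a median of 5.60. The median of all probe sets with 1 symbol was 5.75. The 20 probe sets named for oligodendrocyte and myelin genes, abundant in the midbrain, had a median of 4.23, at percentile 0.79 among random lists of the same size. The 26 named for dopaminergic neuron genes had a median of 5.62, at percentile 40.4. The 11 named for GABAergic neuron genes had a median of 8.98, above all 10000 random lists. Of 38 lists of cell type and pathway genes with at least 5 probe sets, 4 lay outside the middle 95% of random lists, where chance gives 1.9. The correlation between any 2 arrays over all probe sets was 0.975 to 0.992. Gene names were therefore not used for the comparisons between groups, except in alternatives run with the names as listed, and the results are for probe sets whose gene is unknown here.

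**Figure D1:**
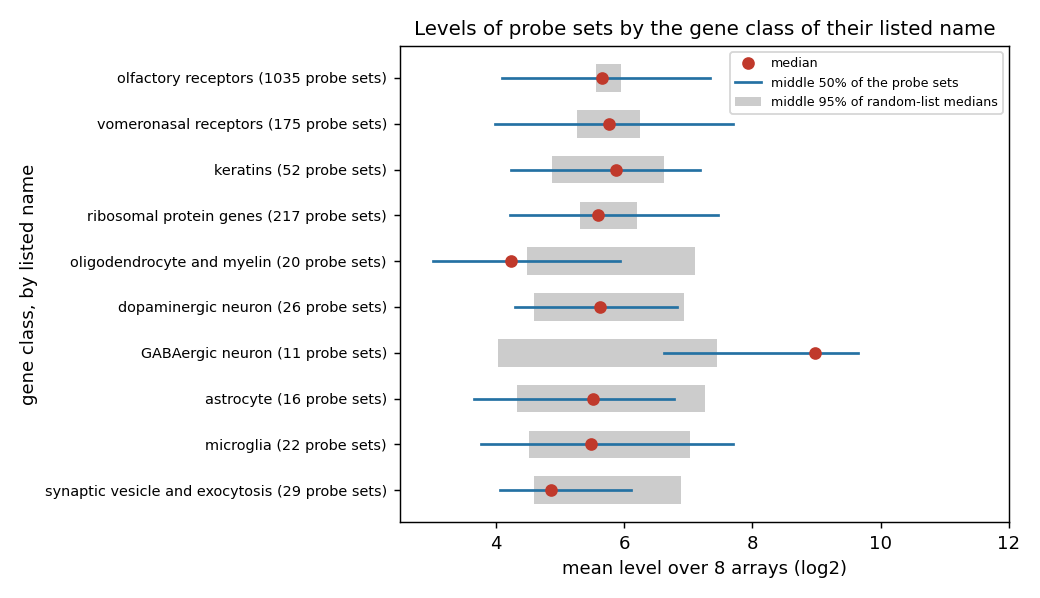
Mean log2 level over the 8 arrays (horizontal axis) of probe sets grouped by the gene class of their listed name (vertical axis); red points are medians, blue lines span the middle 50% of the probe sets, and grey bars span the middle 95% of the medians of 10000 random lists of the same size. The olfactory receptor median of 5.66 and the ribosomal protein median of 5.60 both lie within the grey bars, while the oligodendrocyte and myelin median of 4.23 lies below its bar and the GABAergic median of 8.98 above it.

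The deposited levels differed between arrays as a whole. The median log2 level was 4.09 in control replicate 1 and 5.40 in control replicate 2. It was 5.83 and 5.87 in the MPTP mice, 5.65 and 6.00 in the acupoint mice, and 5.54 and 5.503 in the non-acupoint mice. Unless stated otherwise, comparisons were made after quantile normalization, over 21347 probe sets.

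**Figure D2:**
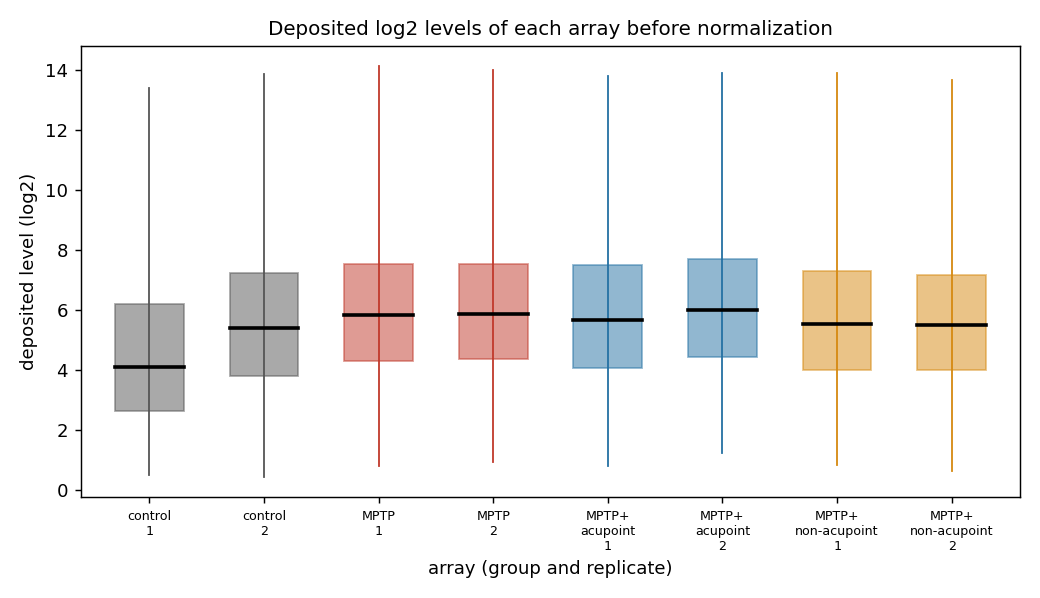
Deposited log2 levels (vertical axis) of each of the 8 arrays (horizontal axis), before normalization; boxes span the middle 50% of the probe sets, black bars are medians, and lines run from the lowest to the highest value. Control replicate 1 had a median of 4.09, and the medians of the other arrays ran from 5.40 to 6.00.

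MPTP mice were compared with control mice to ask what the toxin changed in the substantia nigra. No probe set passed the test (limma, Benjamini-Hochberg adjusted p under 0.05), and the lowest adjusted p was 0.699. At an unadjusted p under 0.05 there were 1438 probe sets, or 6.74% of those tested, where chance alone gives 1067. That count was 840 without MPTP replicate 1, 644 without MPTP replicate 2 and 3804 without control replicate 2. With only the 4 arrays compared, 1092 had an unadjusted p under 0.05 and 0 passed (limma, lowest adjusted p 0.922). The log2 differences had a standard deviation of 0.19 over probe sets, against a median standard error of 0.13. That standard error pools the spread of the 4 groups and was the same in each comparison. The control pair was the widest, so the pooled value can understate the spread here. The 2 values are therefore not evidence of changes beyond noise. A total of 120 probe sets differed by at least 1.5-fold with no overlap between the groups, 88 of them higher and 32 lower in MPTP mice, but the other ways of dividing the same 4 arrays gave 112 and 122. The largest positive difference among probe sets at unadjusted p under 0.01 without overlap was that of probe set 10518561, with a log2 level of 5.05 ± 0.39 in MPTP mice and 3.34 ± 1.47 in control mice (SD, n = 2 each), a difference of 1.71 with a standard error of 0.52. It was 0.67 without control replicate 1 and 2.74, then passing, without control replicate 2 (limma adjusted p = 0.628 and 0.0243). The largest negative one was that of probe set 10590071, at 3.64 in both MPTP mice and 4.47 ± 0.45 in control mice (SD, n = 2), a difference of -0.82 with a standard error of 0.24. It was -0.51 without control replicate 1. After quantile normalization of all arrays both probe sets had an adjusted p of 0.699 in limma. As deposited, where the array medians add 1.104 log2 to every difference, the first was 2.53 and passed (limma adjusted p = 0.000737), and the second was 0.32, of opposite sign. Without control replicate 2 the comparison, then resting on control replicate 1 alone, gave 38 probe sets. On the values as deposited, the setting planned beforehand, it gave 2353 probe sets, all of them higher in MPTP mice, on a median difference of 0.89 log2 over all probe sets.

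Acupuncture at GB34 and LR3 was compared with MPTP alone to ask whether it changed expression after the toxin. No probe set passed the test (limma, lowest adjusted p 1), and 418 probe sets, or 1.96%, had an unadjusted p under 0.05, where chance gives 1067. That spread takes in the control pair, the widest. With only the 4 arrays compared, 998 had an unadjusted p under 0.05 and 0 passed (limma, lowest adjusted p 0.096). The values as deposited, the setting planned beforehand, gave 33 at an unadjusted p under 0.05, and 2 probe sets passed, named here after their values were seen: 10477644, with a difference of 2.58 (adjusted p = 0.00019), and 10555179, with 3.31 (adjusted p = 1.21e-08). That fit set 1 SD of 0.46 for all probe sets, where their own SDs within groups were 1.45 and 1.90, and after quantile normalization their differences were 2.62 and 3.33, each at a limma adjusted p of 1. A total of 68 probe sets differed by at least 1.5-fold without overlap, 22 of them higher and 46 lower in the acupoint mice, against 44 and 47 under the other divisions of the 4 arrays. Among probe sets at unadjusted p under 0.01 without overlap, 10549849 had the largest negative difference, with a log2 level of 5.69 ± 0.12 in acupoint mice and 7.31 ± 0.11 in MPTP mice (SD, n = 2 each). The difference was -1.61 with a standard error of 0.32. Its control levels were 6.51 and 6.47, and its levels in the non-acupoint mice were 7.05 and 5.80. Without either non-acupoint array, which changes only the estimate of the spread, this probe set was the 1 that passed (limma adjusted p = 0.0366). Within the same limits probe set 10590071 had the largest positive difference, 0.85 with a standard error of 0.24. It is the probe set with the largest negative difference between MPTP and control mice, and both differences rest on the same 2 MPTP levels. They are therefore not independent signs of a reversal. Its levels were 4.70 and 4.29 in the acupoint mice, and 4.50 and 3.95 in the non-acupoint mice.

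Needling at the hips was compared with MPTP alone in the same way. No probe set passed the test (limma, lowest adjusted p 0.999), and 454 probe sets, or 2.13%, had an unadjusted p under 0.05, where chance gives 1067. With only the 4 arrays compared, 761 did and 0 passed (limma, lowest adjusted p 0.992). With the values as deposited 0 passed, and 41 had an unadjusted p under 0.05. A total of 41 probe sets differed by at least 1.5-fold without overlap, 9 of them higher and 32 lower in the non-acupoint mice, against 111 and 39 under the other divisions. Of the probe sets at unadjusted p under 0.01 without overlap, 10467083 had the largest negative difference, with a log2 level of 6.93 ± 1.24 in non-acupoint mice and 8.71 ± 0.03 in MPTP mice (SD, n = 2 each). The difference was -1.79 with a standard error of 0.43. Without non-acupoint replicate 1, it alone passed, at a limma adjusted p of 0.0089, and without non-acupoint replicate 2 its difference was -0.91 at an adjusted p of 1. Within these limits probe set 10515981 had the largest positive difference, 0.86 with a standard error of 0.23, or 0.54 as deposited, where the array medians add -0.33 to every difference.

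Acupoint mice were compared directly with non-acupoint mice to ask whether the place of needling mattered. No probe set passed the test (limma, lowest adjusted p 0.558), and 669 probe sets, or 3.13%, had an unadjusted p under 0.05, where chance gives 1067. With only the 4 arrays compared, 851 did and 0 passed (limma, lowest adjusted p 0.964). The deposited values gave 55 at an unadjusted p under 0.05, and 3 passed, named here after their values were seen: 10371627, 10441556 and 10555179, with differences of 2.86, 2.14 and 2.96 (adjusted p = 4.74e-06, 0.0229 and 2.51e-06) on the same SD of 0.46, where their own were 1.60, 1.38 and 1.90. After quantile normalization the differences were 2.62, 1.90 and 2.61, each at a limma adjusted p of 0.999. A total of 53 probe sets differed by at least 1.5-fold without overlap, 27 of them higher and 26 lower in the acupoint mice, and the other divisions of these arrays gave 43 and 173. The largest differences each way at unadjusted p under 0.01 without overlap were those of 2 probe sets. Probe set 10564077 was at a log2 level of 8.27 ± 0.10 in acupoint mice and 7.15 ± 0.45 in non-acupoint mice (SD, n = 2 each), a difference of 1.12 with a standard error of 0.19. Probe set 10381107 was at 5.44 ± 0.52 and 6.50 ± 0.13 (SD, n = 2 each), a difference of -1.06 with a standard error of 0.24. The latter difference was -0.69 without acupoint replicate 1. After quantile normalization the effect of the place of needling was thus not detectable with these arrays, which is not evidence that the places act alike.

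The acupoint and non-acupoint mice were also compared with control mice. No probe set passed in either comparison (limma, lowest adjusted p 1.00 and 0.437), and 905 and 1572 probe sets had an unadjusted p under 0.05. With only the 4 arrays of each comparison, 565 and 791 had an unadjusted p under 0.05, where chance gives 1067, and 0 passed. A test of any difference among the 4 groups passed no probe set either, with 821, or 3.85%, at an unadjusted p under 0.05. Without control replicate 2, the acupoint mice differed from control replicate 1 in 66 probe sets and the non-acupoint mice in 149. As deposited these counts were 36 and 2 (the 2 being 10480321 and 10561958, named after their values were seen), and 20 probe sets differed among the 4 groups.

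Mice of a group were not detectably more alike than mice of different groups. The root-mean-square log2 difference between 2 arrays was 0.25 within groups and 0.24 between groups. Of the 105 ways of dividing the 8 arrays into 4 pairs, 81 gave pairs at least as alike as the real groups (exact permutation test, one-sided, p = 0.771). With 1 array left out the exact p ran from 0.0952, without control replicate 2, to 0.971, without MPTP replicate 2. Among the 6 arrays from MPTP-treated mice, 10 of 15 divisions did (exact p = 0.667), where the smallest p the design allows is 0.0667. The MPTP mice differed by 0.17, the acupoint mice by 0.22, the non-acupoint mice by 0.26 and the control mice by 0.32. Control replicate 2 was closest to acupoint replicate 1, at 0.19. On the values as deposited the exact p over all 8 arrays was 0.0476.

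**Figure D3:**
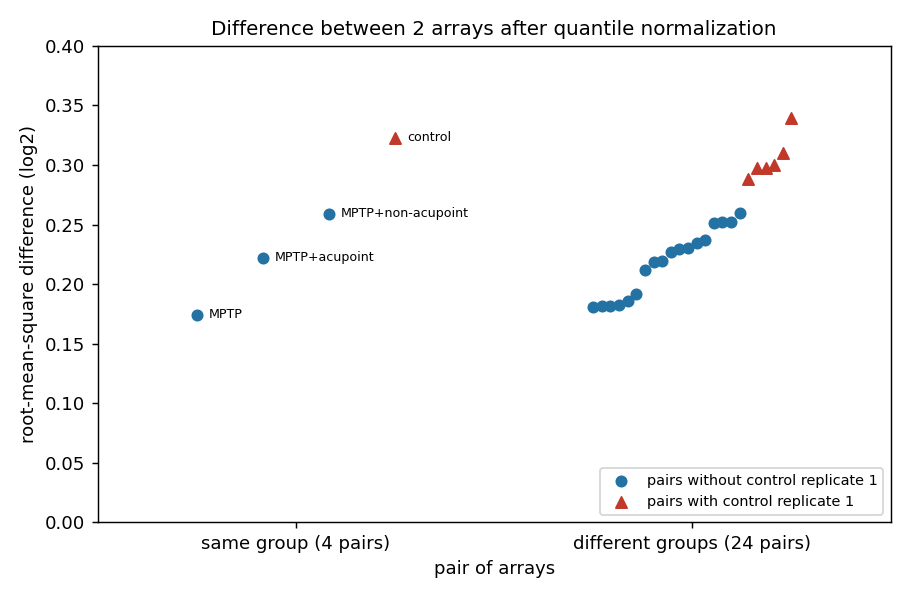
Root-mean-square log2 difference (vertical axis) of each pair of arrays after quantile normalization, for the 4 pairs of the same group and the 24 pairs of different groups (horizontal axis); each point is 1 pair, and red triangles are pairs that include control replicate 1. Pairs of the same group ran from 0.17 for MPTP to 0.32 for control, within the range of pairs of different groups except for the MPTP pair.

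A reversal of the MPTP differences by acupuncture would give opposite signs in the comparison of MPTP with control and in that of acupuncture with MPTP. The log2 differences of these comparisons correlated across probe sets with r = -0.470 for acupoints and r = -0.348 for non-acupoints (probe sets are not independent replicates). Both comparisons share the MPTP arrays, which alone gives a negative value. The covariance was -0.0127 for acupoints. In 100 simulations of unchanged groups, each array was a random mix of the replicate differences of the 4 groups, the wider control pair included. They gave a mean of -0.0125, with a middle 95% from -0.0584 to 0.01002. For non-acupoints the covariance was -0.00953, against a simulated mean of -0.0142 and a range from -0.0673 to 0.0142. The spread of the MPTP arrays alone gives -0.00758, and both covariances were more negative than that. The 2 simulated means estimate the same value and differ only by the random draws. The simulated range is wide, with correlations from -0.985 to 0.674 for acupoints, since each array mixes only 4 patterns. It therefore excludes little. With 1 MPTP array in each comparison, so that none was shared, the covariance was -0.00562 and -0.0047 for acupoints under the 2 ways of dividing the arrays, and -0.00433 and 0.000407 for non-acupoints. No interval was computed for these values.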

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

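The test of whether arrays of a group are alike, cyclic loess, all probe sets of the table, crossed replicate numbers, the division of the MPTP arrays and the deposited values without their offset were chosen after the data were seen. The counts that passed limma's test were 0 in each comparison under every filter, moderation, weighting, covariate and gene rule, and under median-centring and cyclic loess. At an unadjusted p under 0.05 the counts were 821 among the 4 groups, 1438 for MPTP minus control, 418 for acupoint minus MPTP, 454 for non-acupoint minus MPTP, 669 for acupoint minus non-acupoint, 905 for acupoint minus control and 1572 for non-acupoint minus control. Chance gives 1067. With 1 array left out they ran, in that order, from 474 to 2869, 644 to 3804, 229 to 726, 238 to 1343, 317 to 1493, 588 to 3700 and 895 to 4092, all but the third on both sides of chance. Other alternatives gave 438 to 5513, 16 to 10389, 33 to 1100, 21 to 857, 17 to 1193, 26 to 12083 and 39 to 4772. With a 1.5-fold difference without overlap the 6 comparisons gave 120, 68, 41, 53, 105 and 139, where the other divisions of the same arrays gave up to 122, 47, 111, 173, 263 and 243. As deposited the adjusted counts were 20 among the 4 groups and 2353, 2, 0, 3, 36 and 2 in the comparisons, all of these higher in the first-named group. There the median difference was 0.89, 0.05, -0.31, 0.35, 0.93 and 0.58 log2, and limma set 1 SD of 0.46 for all probe sets. The exact permutation p for arrays of a group being alike was 0.0476 as deposited, 0.0952 to 0.971 with 1 array left out and above 0.05 elsewhere. The difference of probe set 10590071 between MPTP and control was 0.32 as deposited, reversed by the 1.104 log2 that the array medians add to every probe set. After removing only each array's median no probe set passed, and the exact p was 0.267. Removing only the offset and keeping that SD left 1, 2, 0, 2, 3 and 0, so the 2 calls for acupoint minus MPTP rest on the SD.

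Leaving out each array in turn, with a lone mouse assumed to vary like the other groups, gave 0 to 38 probe sets for MPTP minus control, 0 to 66 for acupoint minus control and 0 to 149 for non-acupoint minus control. Each highest count came without control replicate 2, and without control replicate 1 each was 0. The range was 0 to 1 for acupoint and for non-acupoint minus MPTP, where the 1 came without a non-acupoint array. The covariance of MPTP minus control with acupoint minus MPTP ran from -0.0225 to -0.00783, and with non-acupoint minus MPTP from -0.0174 to -0.00736, the most negative without MPTP replicate 1, as fewer shared arrays give by construction. For acupoints it was -0.0224 as deposited and under median-centring, which give 1 value by construction and were not simulated, and -0.0212, or -0.0168 for non-acupoints, over all probe sets of the table. With the MPTP arrays divided, so that no shared array adds to it, it was -0.00562 and -0.0047 for acupoints, and -0.00433 and 0.000407, a reversed sign, for non-acupoints.

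Deviations of same-numbered mice correlated between groups from -0.203 to 0.125, the highest between MPTP and acupoint mice. No interval was computed for these correlations, so whether the replicate numbers pair the mice was not settled. With the replicate block 0 probe sets passed in each comparison. Crossing the numbers of acupoint mice with control mice and with non-acupoint mice, where the correlation was under -0.1, also gave 0 and 0.

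With the gene names as listed, which do not go with the levels, 0 of 14953 genes passed. Of 37 lists, limma's camera with its preset correlation called 0, 0, 0 and 1 in the first 4 comparisons. The 1 was the immediate early gene list for acupoint minus non-acupoint (20 members, adjusted p = 0.00897; adjusted p = 0.777 with an estimated correlation). That count was 0 with an estimated correlation, with fry, without the filter and as deposited, and 0 to 1 when each array was left out. As deposited, 1 list was called for MPTP minus control. The cause was not tested, and the lists were not rerun on only the 4 arrays compared or with robust moderation.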

Other observations

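The tests of shifted values, of brightness and group label for control replicate 1, and of treatment group and brightness of the second cluster were chosen after the result was seen. No biological explanation was tested for the first 2 patterns.

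The gene names listed for the probe sets did not go with the levels. A probe annotation in random order is argued against by the 94.3% of neighbouring named IDs that lie on the same chromosome, against 5.59% if shuffled, but an annotation displaced in blocks is not. Whether values and IDs came out of register stays open: with the values moved against the IDs by up to 2000 places either way, in file order or reversed, the highest correlation of same-symbol probe sets was 0.140, so no such move restored the names, and other reorderings were not excluded.

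Control replicate 1 stood apart from the other arrays, with a mean root-mean-square log2 difference to them of 0.308 after quantile normalization, against 0.216 to 0.264 for the other arrays. Overall brightness of the array stays open: control replicate 1 was the dimmest array and the farthest in 3 of 5 equal parts of the probe sets by level, the dimmer ones, but in the brighter ones it was at 0.249 and 0.202, below the highest other array at 0.254 and 0.223; this test replaced one on the mean difference that had counted against brightness, and its bounds were set with these values known. The other 7 arrays were looked at afterwards, under a bound that was dropped because it was set with the value known. Among these 7, dimmer arrays lay farther on average from the rest, with rho = -0.786 (exact permutation p = 0.0480) and r = -0.643 (exact permutation p = 0.112). Without the 2 arrays farthest from the median r was -0.725. These values decide nothing here. A label of another group stays open: it was closer to 5 of the 6 arrays of other groups, the nearest at 0.288, than to control replicate 2 at 0.323, but farther from each than the 0.259 of the widest other replicate pair. Noise in dim probe sets stays open: its distance was 1.52 times the median of the other arrays in the dimmest 20% of probe sets and 1.22 times in the brightest 20%, between the bounds of 1.1 and 1.3 set beforehand, and the mouse, its dissection and its RNA were not tested.

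The most variable probe sets varied together, in their largest cluster in a way that did not follow the groups. Of the 300 most variable, clustered at a correlation of 0.7, the largest cluster held 68, with mean deviations of 1.02 in acupoint replicate 1 and -0.42 in acupoint replicate 2, and of -0.52 and 0.63 in the non-acupoint mice. In each of the 3 largest clusters the widest difference within a group exceeded the range of group means at least 1.70-fold. That ratio sets differences of single arrays against means of 2 arrays, which raises it. In the clusters of 51 and 22 probe sets both quantities rest on control replicate 1, at -1.03 and 0.98. There the ratio cannot decide about treatment group. In the largest cluster it was 2.39, and the replicates had opposite signs in the acupoint and in the non-acupoint mice. This argues against treatment group for that cluster. Brightness of the array is argued against for the largest cluster, whose mean followed the deposited medians over 8 arrays with Spearman's rho = -0.167 (exact permutation p = 0.703) and r = 0.114 (exact p = 0.860; -0.372 without the 2 arrays farthest from the median). It may account for the second cluster of 51, low in control replicate 1, with rho = 0.905 (exact p = 0.00456) and r = 0.963 (exact p = 0.00317; 0.783 without the 2 farthest arrays), or, Benjamini-Hochberg adjusted over 3 clusters, 0.0137 and 0.00952.

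The third cluster held 22 probe sets, at 0.98 in control replicate 1 and -0.26 in control replicate 2. Its mean followed the deposited medians with r = -0.779 (exact permutation p = 0.119) and rho = 0.238 (exact p = 0.582), and r was 0.906 without the 2 arrays farthest from the median, so its sign rests on those arrays.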
